A study of Arabidopsis thaliana with 32 samples.

How the data were processed

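RNA sequencing was analysed from roots and rosettes of Arabidopsis thaliana seedlings of 4 lines. The IMA1 OE and IMA3 OE lines are labelled as overexpressors of IRON MAN peptides, small peptides known to promote the iron deficiency response. The opt3-2 line carries an insertion at OPT3, a phloem transporter known to load iron for redistribution. The control line expresses EYFP, a yellow fluorescent protein, from the constitutive 35S promoter. Per the labels, seedlings grew on plates for 10 days with full iron supply and were harvested 72 h after transfer to control or iron-deficient plates. Iron was left out of the deficient medium and ferrozine, a chelator of ferrous iron, was added. The labels give its concentration as 100 µM in the treatment protocol and 300 µM in the series design, and the difference was not resolved here. The source field of the rosette samples reads roots, while their titles and tissue fields read rosettes, and the titles were followed. RNA integrity numbers per the labels were 9.8 to 10 for roots and 8.3 to 8.7 for rosettes.

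Each of 16 groups (4 lines, 2 media, 2 tissues) had 2 replicate libraries, 32 in all. The authors deposited 26 tables, each comparing 2 groups of the same tissue and each including an EYFP group. Every table held values for 33611 features, of which 33607 were genes and 4 were inserted constructs. The deposited values per library are on the RPKM scale (reads scaled by transcript length and library size) by the authors, a unit that no column header names and that was read from the values. The tables also hold the authors' log2 fold change of group means, unitless on the log2 scale, and the authors' p-value of a Z-test, which was not adjusted for multiple testing. The submitters' processing notes list bcl2fastq 1.8.4, Trimmomatic 0.35, Bowtie2 2.0.6, edgeR 3.12.1 and limma 3.26.9, with the TAIR10 genome. The sorted values of the 4 libraries of a table nearly coincided, as they would after being equalised by the authors. The same library therefore differed slightly between tables, by a median SD of at most 0.0294 on the log2 scale. Except in the list test with an estimated correlation, fold changes were computed inside a table and levels from different tables were not tested.

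Read counts were not given and whole counts could not be recovered from the values. The depth of each library is therefore unknown, and no interval or detection limit that needs it is given. Precision rests on the spread between libraries.

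Values were transformed to log2(RPKM + 0.5), a scale on which fold changes of weakly expressed genes are understated. Genes with a mean of at least 0.5 RPKM over the 16 libraries of a tissue were tested, 20577 in roots and 19521 in rosettes. This filter was chosen after the data were seen, because 7118 genes in roots and 7602 in rosettes had no spread at all between replicates, which made the model of the spread unreliable. The version with all genes is among the alternatives. The fold change of each comparison came from its own table, and the residual spread from all 8 groups of the tissue, with 8 residual degrees of freedom. The spread was moderated toward a trend with expression by the squeezeVar function of limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8), and 2-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was counted as higher or lower at an adjusted p under 0.05. The same limma-type test was used for every comparison. P-values measure only the spread between these libraries, since the labels do not say whether replicates came from separate cultures.

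For each tissue, the comparisons were the response of the EYFP line (deficient against control medium), each other line against EYFP on control medium and on deficient medium, each line on control medium against EYFP on deficient medium, the response within each other line, and the difference between that response and the response of EYFP (the interaction). The last 2 kinds use table pairs, sharing an EYFP group in the former only. Except for the filter and the alternatives named below as added, the groups, comparisons, test and gene lists were fixed before the data were examined. Because all lines were compared with the same 2 EYFP libraries, overlaps between lines were set beside 20 simulated draws in which only the shared libraries link the comparisons.

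A total of 25 gene lists with 296 members were fixed before the data were examined. They cover iron deficiency regulators, iron uptake and coumarin secretion, iron transport and chelation within the plant, iron storage, iron-sulfur cluster assembly, superoxide, peroxide and copper proteins, copper uptake, zinc transport, phosphate starvation, photosynthesis, tetrapyrrole synthesis, plastid and mitochondrial retrograde signalling, leaf senescence, heat shock, jasmonate and wound response, salicylate, camalexin and pathogen response, ethylene, flavonoid and anthocyanin synthesis, aliphatic glucosinolate synthesis, the circadian clock, dividing cells, root hair cells, the root endodermis, phloem, and xylem and secondary wall. Lists were tested with camera of limma at a preset correlation between genes of 0.01. A separate fit across tables used a correlation estimated from the libraries. Adjusted p-values for lists are over the lists of 1 comparison. Counts called "adjusted over the list alone" repeat the adjustment within its members.

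Genes named in the text follow a rule fixed before the data were examined. They are IMA1, IMA3 and OPT3 in each comparison of their lines, the 5 genes with the largest fold change in each direction among protein-coding genes with a symbol and above-median expression that passed the test, up to 4 members with the smallest p of each list discussed, and the 5 genes with the smallest p in each direction for the interactions. Genes outside this rule are said to have been chosen after their values were seen. Symbols came from the annotation of TAIR10.1, matched by identifier for 32835 of the 33611 features, while values are those of the authors on TAIR10. No coordinates were used.

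The method was tested on data simulated with the spread of these libraries and 200 changed genes in each of 5 draws. In the EYFP response, 55.6%, 84.4%, 99.2% and 95.6% of genes changed 1.5-, 2-, 4- and 8-fold were recovered in roots, with 3.68% false calls. The same folds gave 21.2%, 68.8%, 92.4% and 96% in rosettes, with 4.53% false calls. For the opt3-2 interaction, recovery was 30.8%, 66.8%, 94% and 92.8% in roots and 4%, 39.2%, 78.8% and 87.2% in rosettes. False calls were 3.13% and 5.08%. A list raised 1.5-fold was called in 20 of 20 draws. Unchanged lists were called in 7 of 480, 5 of 480, 4 of 454 and 5 of 454 tests. Rates may differ for correlated genes.

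Alternatives fixed before the data were examined were an adjusted p of 0.01, a limit of 2-fold, leaving out the genes of lowest expression in each table, the deposited Z-test adjusted over all genes, median-centred fold changes, median-ratio scaling, a pseudocount of 1, a block for replicate number, each library left out in turn, a conservative standard error, the route through the other EYFP group, and 4 other versions of the list test. Alternatives added after the data were seen were all genes tested, the spread of the compared groups alone, the library with the most plastid transcripts left out, and the estimated correlation for lists. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. All columns of the tables were read. The 4 construct features were left out of the tests because each belongs to 1 line.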

Results

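The transcriptomes of Arabidopsis roots and rosettes were compared between a control line expressing EYFP and 3 lines known to accumulate iron, IMA1 OE, IMA3 OE and opt3-2, each on control medium and after 3 days on iron-deficient medium. Every group had n = 2 libraries. Levels are deposited RPKM as mean ± SD, changes are log2 fold changes with their standard error (SE), and adjusted p is from limma. Where calls ended with 1 library left out, a bare value in brackets is the highest adjusted p reached.

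In EYFP roots, transcripts of iron acquisition genes rose under iron deficiency. IRT1 (AT4G19690), the main ferrous iron importer of the root epidermis, rose from 17.8 ± 6.77 to 881 ± 64.5 RPKM (log2 fold change 5.64, SE 0.24, adjusted p = 3.49e-07). FRO2 (AT1G01580), the ferric chelate reductase, rose from 13.1 ± 3.89 to 661 ± 10.3 RPKM (5.63, SE 0.21, adjusted p = 1.82e-07). Of 19 measured genes of iron uptake and coumarin secretion 18 rose and 0 fell, and 19 rose when adjusted over the list alone. CYP82C4, an enzyme of the coumarin pathway, rose by 7.08 (SE 0.38, adjusted p = 1.05e-06) and MYB72, a transcription factor of coumarin secretion, by 6.67 (SE 0.32, adjusted p = 5.92e-07). Of 18 regulators of iron deficiency 13 rose, or 14 with 1 fall when adjusted over the list alone, with bHLH100 at 6.46 (SE 0.33), IMA3 (AT2G30766) at 4.95 (SE 0.34) and IMA1 (AT1G47400) at 3.19 (SE 0.38). Both lists were called by camera, with adjusted p = 1.61e-271 for uptake and 5.91e-73 for regulators, and adjusted p = 0.00734 and 0.00694 with an estimated correlation.

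Genes of iron storage moved the other way in EYFP roots. Of 7 measured members 5 fell, or 6 when adjusted over the list alone. The ferritin gene FER1 (AT5G01600) fell from 101 ± 37.8 to 31.2 ± 10.6 RPKM (-1.67, SE 0.25, adjusted p = 0.00316), FER4 by -1.13, FER2 by -1.27 and the vacuolar iron transporter-like gene VTL2 by -1.41. Camera called this list (adjusted p = 2.94e-09), with adjusted p = 0.0961 with an estimated correlation. Of 16 genes of iron transport and chelation within the plant 6 rose and 1 fell, or 8 and 3 when adjusted over the list alone, among them FRO3 (2.62) and the nicotianamine synthase gene NAS1 (2.11), which rose, and YSL2 (-0.99), which fell. The list had adjusted p = 1.07e-06, and adjusted p = 0.0505 with an estimated correlation. OPT3 (AT4G16370) rose by 2.42 (SE 0.31, adjusted p = 0.00107). The iron superoxide dismutase gene FSD1 (AT4G25100) fell by -1.97 (SE 0.34, adjusted p = 0.00826), while CSD1 (0.75) and the copper chaperone gene CCS (0.54) rose. The superoxide, peroxide and copper list had camera adjusted p = 0.731. Among copper transporters COPT2 rose by 3.74 and ZIP2 fell by -2.32, in a list with a median of -0.34 (adjusted p = 0.782), and among genes of iron-sulfur cluster assembly SUFB fell by -0.73, in a list with a median of -0.03 (adjusted p = 0.47). In the zinc transport list ZIP9 rose (1.86) and ZIP3 (-0.97), ZIP4 (-0.76) and HMA2 (-1.17) fell (adjusted p = 0.102). Further falls by the naming rule were those of LAC7 (-1.28), CYP71B2 (-1.16) and KIN2 (-1.14).

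In total, 530 of 20577 genes passed the test in EYFP roots, 439 higher and 91 lower. The p-values of the authors' deposited table, adjusted over all genes, gave 150. Without EYFP control replicate 1, control replicate 2 or deficient replicate 2 the count was 297, 295 and 282. The calls of FSD1, LAC7 and KIN2 ended without single libraries: for FSD1 adjusted p = 0.0953 without control replicate 2, 0.0545 without deficient replicate 1 and 0.0666 without deficient replicate 2, for LAC7 0.0848 without control replicate 1 and 0.0564 without deficient replicate 2, and for KIN2 0.0955, 0.0624 and 0.124 without control replicate 1, control replicate 2 and deficient replicate 2. Calls above also ended for VTL2 (0.279), ZIP3 (0.151) and ZIP4 (0.155) without control replicate 2, HMA2 (0.253) without deficient replicate 1 and FER2 (0.0845) and SUFB (0.194) without deficient replicate 2.

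**Figure D1:**
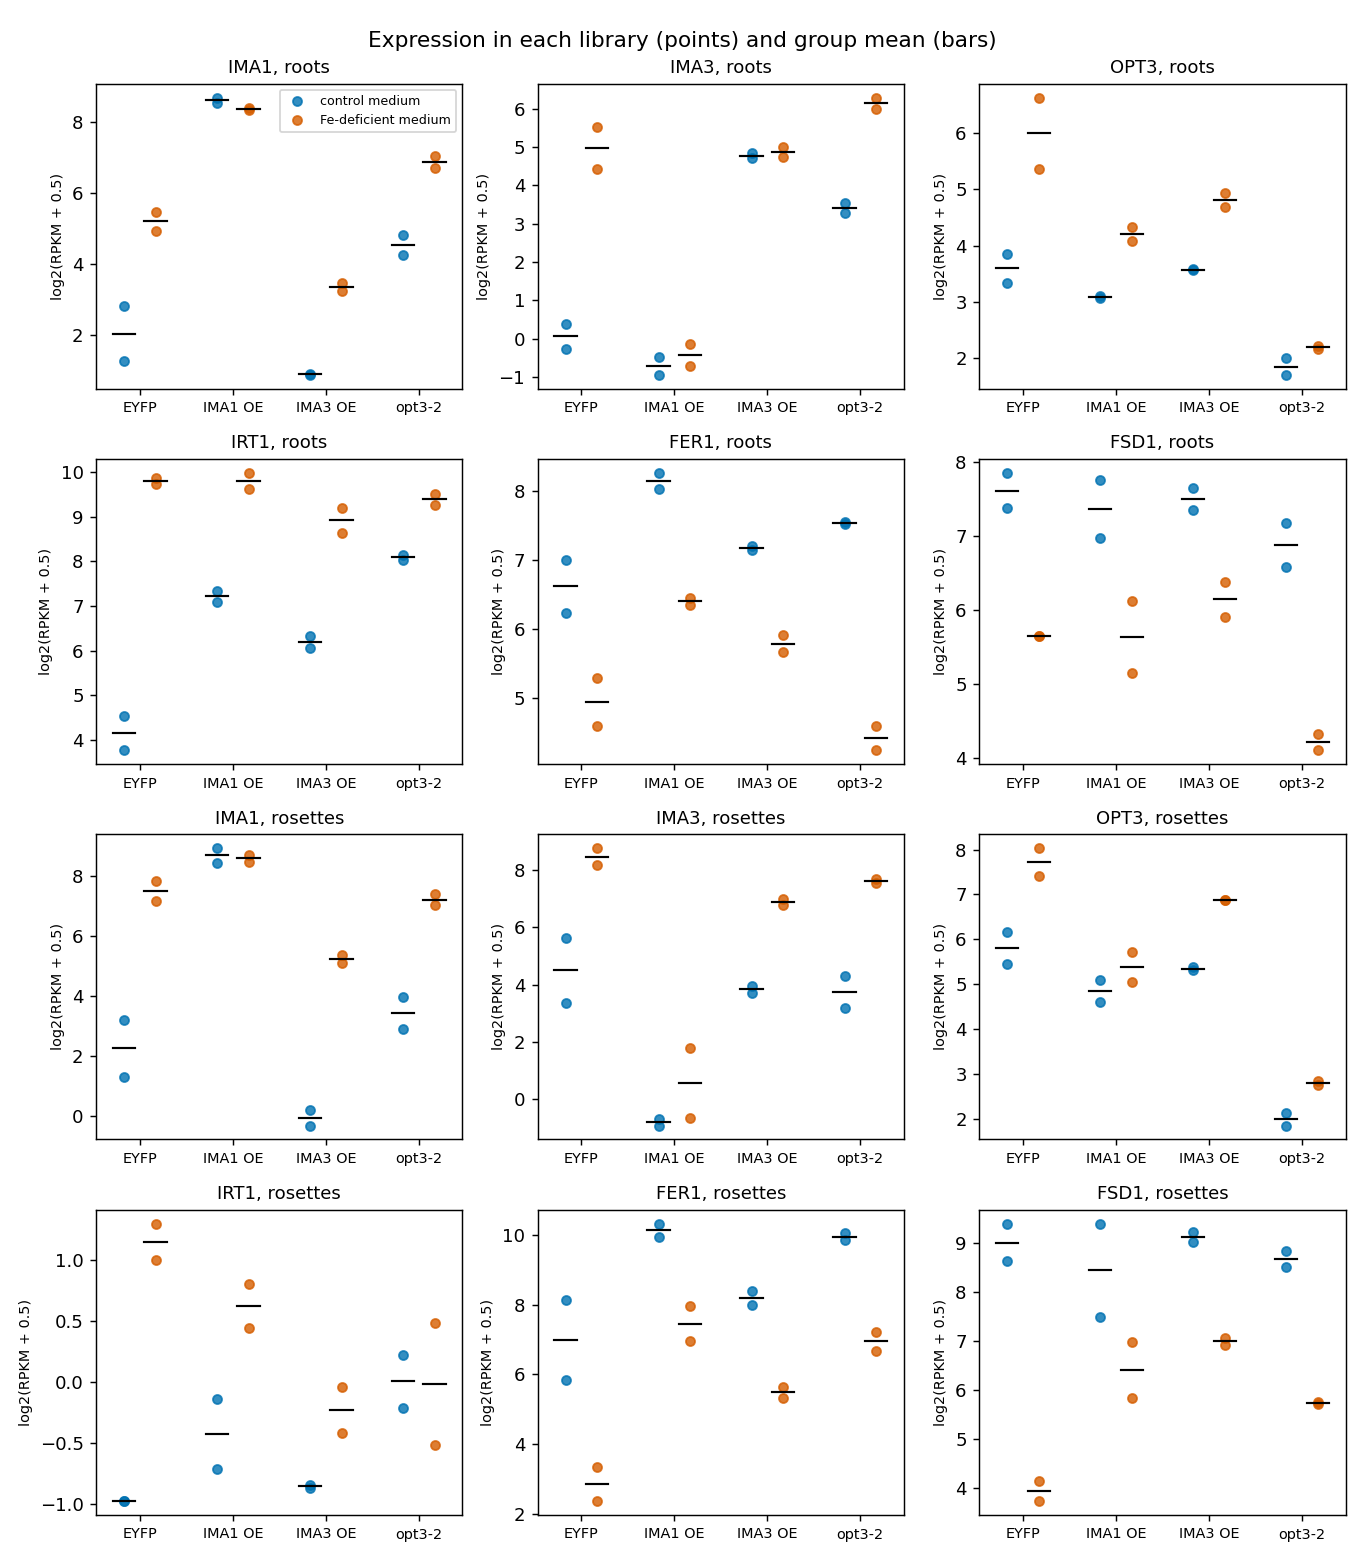
Expression of IMA1, IMA3, OPT3, IRT1, FER1 and FSD1 as log2(RPKM + 0.5) in every library (points) with group means (bars), by line and medium, roots above and rosettes below. In EYFP roots IRT1 lay at 17.8 RPKM on control medium and 881 RPKM on deficient medium, and in EYFP rosettes FER1 lay at 172 and 6.92 RPKM.

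In EYFP rosettes, transcripts of regulators rose under deficiency, and those of FSD1, NEET, FER1 and FER4 fell. Of 18 regulators 9 rose, or 10 with 1 fall when adjusted over the list alone. They included the transcription factor genes bHLH38 (7.33, SE 0.63, adjusted p = 0.000996), bHLH100 (7.17, SE 0.66, adjusted p = 0.00115), bHLH39 (6.61, SE 0.65, adjusted p = 0.00174) and bHLH101 (5.71, SE 0.66, adjusted p = 0.0041), and IMA1 (5.26, SE 0.53, adjusted p = 0.00179). IMA3 was at 4.0 (SE 0.78, adjusted p = 0.0888) and OPT3 rose by 1.95 (SE 0.29, adjusted p = 0.0162). FSD1 fell from 536 ± 187 to 14.7 RPKM (-5.11, SE 0.53, adjusted p = 0.0019), NEET, an iron-sulfur protein gene, by -4.59 (SE 0.48, adjusted p = 0.00208) and FER1 from 172 ± 163 to 6.92 RPKM (-4.19, SE 0.62, adjusted p = 0.0162). ENH1, which encodes a rubredoxin-like protein, fell by -2.67, FER4 by -2.53, and ORG1 rose by 3.46. Of 7 storage genes 2 fell, or 6 when adjusted over the list alone, and of 13 genes of iron-sulfur cluster assembly NEET and SUFB (-2.05) fell. With an estimated correlation, adjusted p was 0.00624 for regulators, 0.00624 for storage and 0.0362 for iron-sulfur cluster assembly. Iron transport and chelation had 5 higher and 1 lower of 19, with ZIF1 (2.43), NAS4 (1.81), NRAMP4 (1.63) and FRO3 (2.39) higher, and adjusted p = 0.221 with an estimated correlation. Iron uptake had 2 higher of 12, FRO2 (1.87) and IRT1 (2.07), with adjusted p = 0.0527 with an estimated correlation. Copper and zinc superoxide dismutase genes and their chaperone rose, with CSD2 at 1.85, CCS at 1.82 and CSD1 at 1.47, in a list that also held 2 falls (camera adjusted p = 0.138).

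In rosettes 66 of 19521 genes passed the test, 34 higher and 32 lower, and the authors' deposited table, its p-values adjusted over all genes, gave 88. Without EYFP control replicate 2 the count was 18 and without deficient replicate 2 it was 26. With the spread of the 2 EYFP groups alone, an alternative added after the data were seen, it was 0 in limma, with 341 genes at an unadjusted p under 0.05, so these calls rest on a spread shared with the other groups. FER1, FER4 and OPT3 lost their calls without control replicate 2 (adjusted p = 0.0667, 0.133 and 0.184) and without deficient replicate 2 (0.226, 0.131 and 0.225). ENH1 reached 0.0667 without control replicate 2, and bHLH101 0.0576 and ORG1 0.064 without deficient replicate 2. Calls also ended for FRO3 (0.0757), NAS4 (0.0667), NRAMP4 (0.0757), IRT1 (0.261) and CCS (0.133) without control replicate 2 and FRO2 (0.17), CSD1 (0.327) and CSD2 (0.0944) without deficient replicate 2. IMA3 passed without control replicate 1 (5.13, adjusted p = 0.0351). The 2 EYFP control libraries differed in FER1, at 56.5 and 282 RPKM, and in IMA3, at 48.3 and 9.85 RPKM. Across tissues, 24 genes were higher in both and 11 were lower in both, of 18383 genes tested in both.

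The EYFP response of the remaining lists was as follows. In roots, root endodermis genes had a median of 0.32 (1 of 6 higher, ESB1 at 0.36, 6 when adjusted over the list alone, camera adjusted p = 1.58e-05, and adjusted p = 0.0961 with an estimated correlation). Photosynthesis genes had a median of -0.46 in roots (0 of 37 passed, adjusted p = 0.00153, and adjusted p = 0.568 with an estimated correlation) and -0.03 in rosettes (adjusted p = 0.0435, and 0.681 with an estimated correlation). Aliphatic glucosinolate synthesis had medians of 0.56 in roots, where CYP83A1 (0.57) rose, and 0.27 in rosettes, with adjusted p = 0.329 and 0.395 with an estimated correlation. Tetrapyrrole synthesis had -0.22 in roots, where HEMA2 rose (0.42) and HEMA1 fell (-0.77), with adjusted p = 0.497 with an estimated correlation, and -0.03 in rosettes. Zinc transport had -0.54 and -0.36 in roots and rosettes, where its adjusted p was 0.0155, and adjusted p = 0.203 with an estimated correlation. Flavonoid and anthocyanin synthesis had -0.36 and -0.40, with adjusted p = 0.0198 in rosettes, and adjusted p = 0.549 with an estimated correlation. For circadian clock genes the medians were 0.05 and 0.15, for ethylene 0.11 and 0.16, for heat shock -0.38 and -0.48, for dividing cells -0.17 and -0.11, for jasmonate and wound response -0.16 and -0.15, for leaf senescence -0.14 and -0.08, and for phosphate starvation -0.23 and -0.07. Phloem had -0.02 and 0.14, xylem and secondary wall 0.05 and 0.02, retrograde signalling 0.03 and 0.05, salicylate, camalexin and pathogen response 0.20 and 0.03, and root hair cells 0.12 in roots. From circadian clock to root hair cells, no member of these lists passed the test over all genes in limma. The calls in roots ended for ESB1 (0.12) and CYP83A1 (0.274) without control replicate 1 and HEMA1 (0.0523) and HEMA2 (0.169) without deficient replicate 2.

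On control medium, IMA1 OE roots carried high IMA1 and raised iron uptake genes. IMA1 was at 4.33 ± 3.36 RPKM in EYFP and 388 ± 31.1 RPKM in IMA1 OE (6.52, SE 0.38, adjusted p = 1.01e-05), a value that can include reads of the transgene. IRT1 rose to 149 ± 17.7 RPKM (3.04, SE 0.24, adjusted p = 0.000168), FRO2 by 2.76 (SE 0.21, adjusted p = 0.00011), bHLH100 by 3.20 (SE 0.33, adjusted p = 0.00107), CYP82C4 by 2.91 (SE 0.38, adjusted p = 0.00548) and bHLH39 by 2.56 (SE 0.34, adjusted p = 0.00671). IMA3 was at -0.79 (adjusted p = 0.893) and OPT3 at -0.51 (adjusted p = 1). Of 19 uptake genes 8 rose (13 when adjusted over the list alone), of 18 regulators 6 rose (8, with 1 fall, when adjusted over the list alone), of 7 storage genes VTL2 (2.06), FER1 (1.51) and VTL1 (1.89) rose (6 when adjusted over the list alone), and of 16 transport genes FRD3 (1.70), NAS1 (1.40) and NAS2 (1.19) rose. These 4 lists each had adjusted p = 0.0327 with an estimated correlation. COPT2 rose (1.36) and HMA2 fell (-1.44), while 0 of 37 photosynthesis genes passed (camera adjusted p = 3.44e-06, and adjusted p = 0.778 with an estimated correlation). In all 76 genes passed, 70 higher and 6 lower, and the authors' deposited table gave 51. The count was 34, 47 and 31 without EYFP control replicate 1, EYFP control replicate 2 and IMA1 OE control replicate 1, and 8 with the spread of the compared groups alone. CYP82C4 reached adjusted p = 0.0517 without EYFP control replicate 1 and 0.0791 without IMA1 OE control replicate 1, and bHLH39 0.0541 without EYFP control replicate 2 and 0.0993 without IMA1 OE control replicate 1. Also lost were FER1 (0.232) without EYFP control replicate 1, VTL1 (0.333), VTL2 (0.181), COPT2 (0.208), HMA2 (0.48) and NAS1 (0.0822) without IMA1 OE control replicate 1 and NAS2 (0.0888) without IMA1 OE control replicate 2.

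IMA3 OE roots on control medium showed a set of the same kind. IMA3 was at 27.3 RPKM against 0.61 in EYFP (4.68, SE 0.34, adjusted p = 0.000225). IRT1 rose from 18.3 to 73 RPKM (2.01, SE 0.24, adjusted p = 0.00815), FRO2 by 1.70 (SE 0.21, adjusted p = 0.00823), bHLH100 by 2.07 (adjusted p = 0.0318), bHLH101 by 1.86 (adjusted p = 0.023) and bHLH38 by 1.60 (SE 0.26, adjusted p = 0.0387). IMA1 was at -1.18 (adjusted p = 0.482). Of 19 uptake genes 3 rose, including MTP3 (0.99), or 11 when adjusted over the list alone. Of 18 regulators 4 rose, or 6 with 2 falls when adjusted over the list alone, and NAS1 (1.18) and NAS2 (1.14) rose among 16 transport genes. All 3 lists had adjusted p = 0.163 with an estimated correlation. In all 42 genes passed, 40 higher and 2 lower, AT3G33528 (-2.03) and AT5G15360 (-1.05), named after their values were seen, and the authors' deposited table gave 40. The count was 12, 15, 7 and 7 without EYFP control replicates 1 and 2 and IMA3 OE control replicates 1 and 2, and 14 with the spread of the compared groups alone. Without any single library of these 4, bHLH100 (adjusted p up to 0.275, without EYFP control replicate 1), bHLH101 (up to 0.201) and bHLH38 (up to 0.299, both without EYFP control replicate 2) no longer passed. IRT1 and FRO2 had 0.0884 without IMA3 OE control replicate 1, 0.0658 without its replicate 2, and 0.051 and 0.075 without EYFP control replicate 1, and IMA1 passed without EYFP control replicate 2 (-1.95, adjusted p = 0.0296). Also lost were NAS1 (0.279) and AT5G15360 (0.258) without EYFP control replicate 1, MTP3 (0.372) without EYFP control replicate 2 and NAS2 (0.238) without IMA3 OE control replicate 2.

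Roots of opt3-2 on control medium had the widest change among the 3 lines in this count. CYP82C4 rose by 4.83 (SE 0.38, adjusted p = 7.96e-05), IRT1 to 270 RPKM (3.91, SE 0.24, adjusted p = 1.35e-05), FRO2 by 3.68 (SE 0.21, adjusted p = 5.92e-06), bHLH100 by 3.37 and the glutathione transferase gene GSTL1 by 3.19 (SE 0.26, adjusted p = 8.05e-05). OPT3 fell from 11.9 to 3.17 RPKM (-1.74, SE 0.31, adjusted p = 0.0218) and CYP71A27 by -0.36 (SE 0.06, adjusted p = 0.0101), while IMA3 (3.35) and IMA1 (2.48) rose. Of 19 uptake genes 12 rose (16 when adjusted over the list alone, adjusted p = 0.0235 with an estimated correlation), and of 18 regulators 9 rose (10 when adjusted over the list alone, adjusted p = 0.0195 with an estimated correlation). Among 16 transport genes 5 rose, including NAS2 (2.2), NAS1 (2.1), NRAMP3 (2.01) and FRD3 (1.58), and OPT3 fell (adjusted p = 0.0228 with an estimated correlation). In the storage list VTL2 (1.81) and VTL5 (1.96) rose, with adjusted p = 0.214 with an estimated correlation, and in the zinc list ZIP1 (0.64), ZIP4 (0.81) and ZIP9 (1.2) rose, with adjusted p = 0.114 with an estimated correlation. COPT2 rose by 2.11. Of the salicylate, camalexin and pathogen list 0 passed over all genes and 5 were higher when adjusted over the list alone (adjusted p = 0.114 with an estimated correlation). In all 200 genes passed, 187 higher and 13 lower, and the authors' deposited table gave 74. Counts without EYFP control replicates 1 and 2 and opt3-2 control replicates 1 and 2 were 92, 111, 96 and 99. OPT3 did not pass without any of these 4 (adjusted p = 0.228, 0.0552, 0.214 and 0.0906 in that order), nor did CYP71A27 (0.104, 0.0742, 0.0548 and 0.101), and IMA1 had 0.115 without opt3-2 control replicate 1. Also lost were ZIP1 (0.142), ZIP4 (0.234) and VTL5 (0.25) without EYFP control replicate 1 and VTL2 (0.158) and ZIP9 (0.319) without opt3-2 control replicate 1.

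A set of 32 genes was higher in roots of all 3 lines on control medium, among them IRT1, FRO2, MTP3, bHLH38, bHLH100, bHLH101, NAS1 and NAS2, and 15 of them were also higher in the EYFP response. Pairs of lines shared 33 (IMA1 OE and IMA3 OE), 58 (IMA1 OE and opt3-2) and 36 (IMA3 OE and opt3-2) higher genes, where independent lists of these sizes would share 0.136, 0.636 and 0.364. The EYFP response shared 36, 16 and 98 higher genes with IMA1 OE, IMA3 OE and opt3-2, against 1.49, 0.853 and 3.99 for independent lists. Without EYFP control replicates 1 and 2, IMA1 OE control replicate 1 and IMA3 OE control replicates 1 and 2 the set of 32 and the 33 of IMA1 OE and IMA3 OE were both 8, 10, 19, 4 and 3. In limma 0, 4, 9, 0 and 0 of the set were then in the EYFP response. The 58 became 28 and 23 without EYFP and IMA1 OE control replicate 1. The 36 of IMA3 OE and opt3-2 became 11, 12, 5 and 4 without the EYFP and IMA3 OE libraries. The EYFP overlap of IMA1 OE was 18, 23 and 12 without the EYFP libraries and IMA1 OE control replicate 1, and that of IMA3 OE 1, 5, 1 and 1 without the EYFP and IMA3 OE libraries. That of opt3-2 was 53, 61, 51 and 57 without EYFP and opt3-2 control replicates 1 and 2. All of these contrasts use the same 2 EYFP libraries, which cannot be split, so part of the excess can come from them. Unchanged groups simulated against those libraries gave 0 shared genes in 20 draws, but such groups yield almost no called genes, so this value does not measure that part.

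Fold changes were also compared across genes, which are not independent replicates, and the simulated values are for unchanged groups of independent libraries. In control roots the pairs of lines had r = 0.612, 0.702 and 0.656 against 0.505 simulated, and covariances of 0.0367, 0.0536 and 0.0479 against 0.0188 simulated. In deficient roots, where pairs shared 6, 6 and 7 higher genes (0.0156, 0.00933 and 0.0117 for independent lists), r was 0.357, 0.498 and 0.297, all below the simulated 0.505, with covariances of 0.0221, 0.0275 and 0.0191 against 0.0188. The EYFP response in roots had r = 0.448, 0.398 and 0.559 with IMA1 OE, IMA3 OE and opt3-2 on control medium, the former 2 below the simulated 0.505, with covariances of 0.0386, 0.0329 and 0.0587. In rosettes, against 0.502 and a covariance of 0.0364 simulated, pairs of lines had r = 0.705, 0.746 and 0.594 on control medium and 0.764, 0.64 and 0.584 on deficient medium, with covariances of 0.0633, 0.0981, 0.0575, 0.0844, 0.07 and 0.045. The EYFP response in rosettes had r = 0.0353, 0.083 and 0.0973 with the lines on control medium, with covariances of 0.00348, 0.00602 and 0.0103, both below the simulated values.

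**Figure D2:**
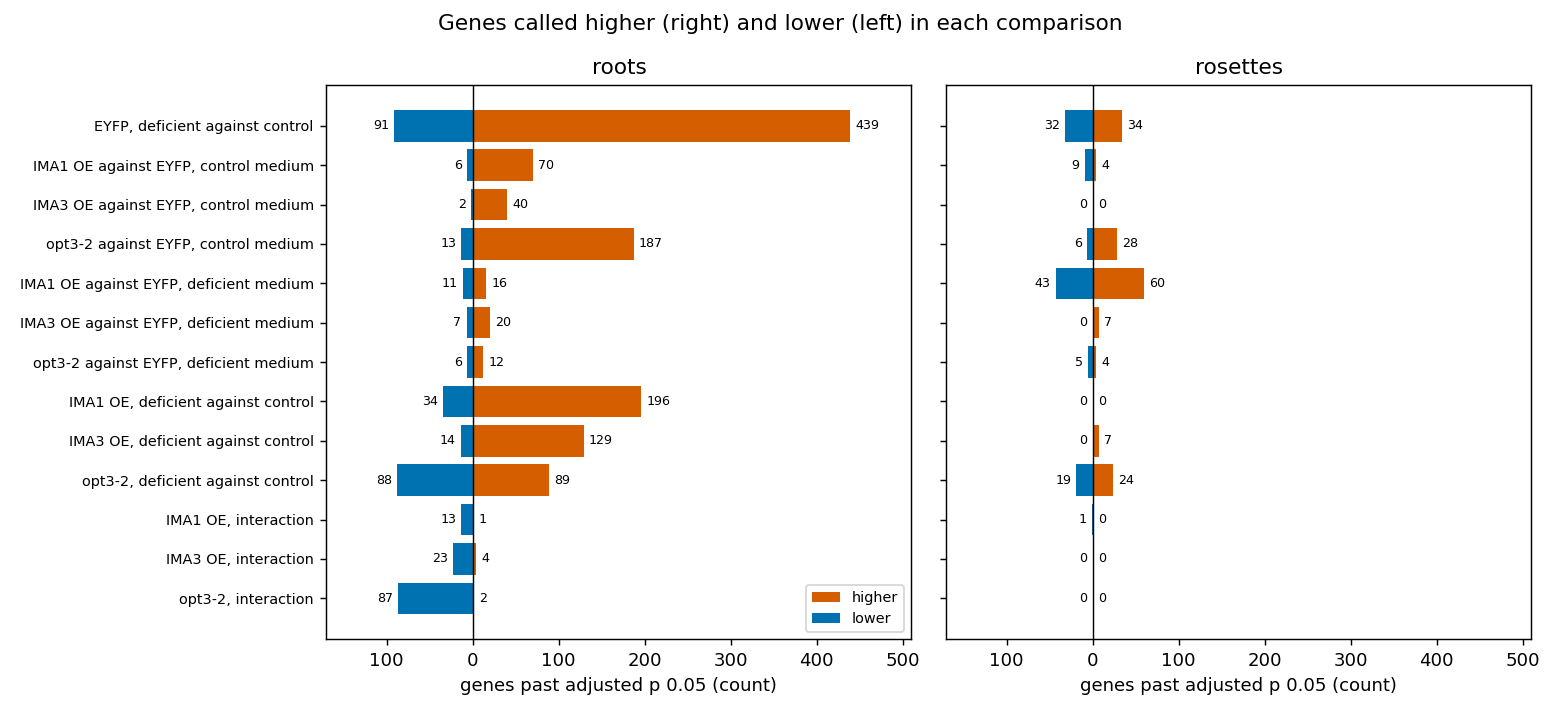
Number of genes higher (right) and lower (left) at an adjusted p under 0.05 in each comparison, for roots and rosettes, with the counts printed at the bars. The EYFP response had 439 higher genes in roots and 34 in rosettes, and the interactions in roots were mostly lower (13, 23 and 87).

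In rosettes on control medium, the gene targeted in the line passed in IMA1 OE and opt3-2. In IMA1 OE, IMA1 rose from 5.52 to 415 RPKM (6.39, SE 0.53, adjusted p = 0.000912), while IMA3 (-5.32, SE 0.78, adjusted p = 0.0479), IMA2 (-3.48, SE 0.47, adjusted p = 0.0343) and DGAT3, a cytosolic acyltransferase gene (-2.49, SE 0.29, adjusted p = 0.0209), fell. No storage gene passed over all genes in limma, and 6 of 7 were higher when adjusted over the list alone, with FER1 at 3.16 (adjusted p = 0.138) and FER3 at 1.40. The lists of storage, leaf senescence, retrograde signalling, salicylate, camalexin and pathogen response, and superoxide, peroxide and copper proteins were each called higher, with 6, 2, 6, 8 and 4 members when adjusted over the list alone and adjusted p = 0.0389 with an estimated correlation. In opt3-2, OPT3 fell from 56.5 to 3.5 RPKM (-3.80, SE 0.29, adjusted p = 0.000351), and the defence-related transcription factor gene WRKY46 (2.03, SE 0.32, adjusted p = 0.0409), ATMDAR2, a monodehydroascorbate reductase gene (0.80, SE 0.12, adjusted p = 0.0329), and SAG13, a senescence-associated gene (3.69, SE 0.60, adjusted p = 0.0468), rose. Its salicylate, camalexin and pathogen list had 8 higher and its retrograde list 5 higher when adjusted over the list alone, with adjusted p = 0.0717 for both with an estimated correlation. The opt3-2 control replicate 2 library held 24319 RPKM of plastid transcripts, against 7421 in the next highest. In IMA3 OE 0 genes passed in limma, 622 had an unadjusted p under 0.05 and the authors' deposited table gave 34, with IMA3 at -0.66 (13.7 RPKM against 28.9 in EYFP) and IMA1 at -2.31 (adjusted p = 1).

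The counts in control rosettes were 13 in IMA1 OE (4 higher, 9 lower) and 34 in opt3-2 (28 higher, 6 lower), and the authors' deposited tables gave 102 and 162. In limma these counts lie below those of roots (76 and 200), and in the deposited tables above them (51 and 74). Beside IMA1, the higher genes in IMA1 OE were AT2G43150 (0.82), AT4G20000 (1.88) and DUR3 (1.51), named after their values were seen. For IMA1 OE the count was 3 without EYFP control replicate 1 and 8 without IMA1 OE control replicate 1. For opt3-2 it was 3, 9, 138 and 4 without EYFP control replicates 1 and 2 and opt3-2 control replicates 1 and 2, and for IMA3 OE 1 without IMA3 OE control replicate 2. With the spread of the compared groups alone the IMA1 OE and opt3-2 counts were 0 and 1 in limma, the former with 1084 genes at an unadjusted p under 0.05. IMA3 in IMA1 OE and DGAT3 lost their calls without EYFP control replicate 1 and IMA1 OE control replicates 1 and 2, with adjusted p = 0.245, 0.424 and 0.125 for IMA3 and 0.117, 0.151 and 0.0615 for DGAT3. Also lost were IMA2 (0.287), AT2G43150 (0.241), AT4G20000 (0.29) and DUR3 (0.424) without IMA1 OE control replicate 1. WRKY46 had 0.265, 0.218 and 0.491, ATMDAR2 0.22, 0.17 and 0.424 and SAG13 0.309, 0.0724 and 0.565 without EYFP control replicates 1 and 2 and opt3-2 control replicate 2.

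On iron-deficient medium, IMA1 OE roots had IMA1 at 327 RPKM against 36.7 (3.17, SE 0.38, adjusted p = 0.00552) while the sister genes were low. IMA3 fell from 33.3 to 0.255 RPKM (-5.40, SE 0.34, adjusted p = 1.62e-05) and IMA2 by -4.25 (SE 0.50, adjusted p = 0.0053), and the nicotianamine synthase gene NAS4 fell by -2.48 (SE 0.36, adjusted p = 0.0229). FER2 (1.49, SE 0.22, adjusted p = 0.0229) and the kinase gene WNK5 (0.97) rose, and OPT3 was at -1.80 (adjusted p = 0.0743). Of 19 uptake genes 0 passed in this comparison (adjusted p = 0.662 with an estimated correlation), of 7 storage genes 1 rose (5 when adjusted over the list alone, adjusted p = 0.067 with an estimated correlation), and of 6 endodermis genes 6 were lower when adjusted over the list alone (adjusted p = 0.067 with an estimated correlation). In IMA3 OE roots, IMA3 was at -0.05 (adjusted p = 1) and IMA1 at -1.80 (adjusted p = 0.122), and 18 of 19 uptake genes and 11 of 18 regulators were lower when adjusted over the list alone, with adjusted p = 0.0697 and 0.063 with an estimated correlation. Plastid genes ATCG00580 and ATCG00920 rose there. Plastid transcripts were at 510 and 2085 RPKM in replicates 1 and 2 and at most 277 in other root libraries. In opt3-2 roots OPT3 fell by -3.83 (SE 0.31, adjusted p = 0.000226) and NYC1, a chlorophyll b reductase gene, by -1.09, with IMA1 at 1.65 (adjusted p = 0.367) and IMA3 at 1.17 (adjusted p = 0.626). Of 37 photosynthesis genes 0 passed over all genes in limma and 23 were lower when adjusted over the list alone, with PETE1 at -1.49 and LHCB1.3 at -2.13 and adjusted p = 0.289 with an estimated correlation.

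In deficient roots 27, 27 and 18 genes passed in IMA1 OE (16 higher, 11 lower), IMA3 OE (20 higher, 7 lower) and opt3-2 (12 higher, 6 lower). The authors' deposited tables gave 34, 72 and 47. The IMA1 OE count was 13 without EYFP deficient replicate 2 or IMA1 OE deficient replicate 1 and 15 without its replicate 2. The IMA3 OE count was 5 without EYFP deficient replicate 2 and 76 without IMA3 OE deficient replicate 1, and the opt3-2 count was 9 without opt3-2 deficient replicate 2. IMA1 in IMA1 OE had adjusted p = 0.0554, 0.0734 and 0.082 without EYFP deficient replicate 1 and IMA1 OE deficient replicates 1 and 2. OPT3 passed without EYFP deficient replicate 1 in IMA1 OE (-2.44, adjusted p = 0.000488) and IMA3 OE (-1.76, adjusted p = 0.0112). With the spread of the compared groups alone the counts were 7, 2 and 7. Calls ended for IMA2 (0.0861) without EYFP deficient replicate 2, NAS4 (0.267) without IMA1 OE deficient replicate 1 and FER2 (0.289) without IMA1 OE deficient replicate 2 in IMA1 OE. They ended for ATCG00580 (0.193) and ATCG00920 (0.193) without EYFP deficient replicate 2 in IMA3 OE and for NYC1 (0.116) without opt3-2 deficient replicate 2.

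Deficient rosettes of IMA1 OE had regulators below those of deficient EYFP. Of 18 regulators 9 were lower than in deficient EYFP rosettes, while IMA1 was at 1.1 (387 against 185 RPKM, adjusted p = 0.672). Among the 9 were IMA3 (-7.88, SE 0.78, adjusted p = 0.000744), IMA2 (-7.22, SE 0.47, adjusted p = 6e-05), bHLH100 (-7.84, SE 0.66, adjusted p = 0.000365) and the E3 ligase gene BTS (-2.83, SE 0.27, adjusted p = 0.000609). That list had 9 lower when adjusted over the list alone and adjusted p = 0.08 with an estimated correlation. FER1 rose from 7.12 to 185 RPKM (4.60, SE 0.62, adjusted p = 0.0063), and FER4 (3.00) and VTL2 (1.84) rose, so that 3 of 7 storage genes were higher, or 6 when adjusted over the list alone (adjusted p = 0.0371 with an estimated correlation). NEET (5.15, SE 0.48, adjusted p = 0.000609), SUFB (2.21) and the ferredoxin gene FD2 (1.2, adjusted p = 0.0477) were higher too. Transport genes had 2 higher and 5 lower, with ZIF1 (-2.67), NAS4 (-2.58), OPT3 (-2.33, SE 0.29, adjusted p = 0.00391) and NRAMP4 (-1.63) lower (adjusted p = 0.13 with an estimated correlation). The superoxide, peroxide and copper list had APX1 (1.56) higher, 4 members when adjusted over the list alone, and adjusted p = 0.043 with an estimated correlation. In opt3-2 rosettes OPT3 fell by -4.91 (adjusted p = 3.43e-05) and NEET rose by 3.60 (adjusted p = 0.0332). In IMA3 OE rosettes IMA3 itself was at -1.58 (118 against 360 RPKM in EYFP, adjusted p = 1), and on control medium its estimate of -0.66 turned to 0.46 (adjusted p = 0.999) without EYFP control replicate 1. The IMA3 construct, counted as a feature of its own, had a mean of 28.3 RPKM there. In that line 7 genes rose, including HCHIB, a basic chitinase gene (1.42), NF-YA10 (1.26) and QQS (1.92), and 9 regulators were lower when adjusted over the list alone (adjusted p = 0.109 with an estimated correlation).

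In deficient rosettes 103 genes passed in IMA1 OE (60 higher, 43 lower), 7 in IMA3 OE and 9 in opt3-2 (4 higher, 5 lower), and the authors' deposited tables gave 176, 95 and 72. In opt3-2 the higher genes were NEET, NAC044 (3.33), AT3G43670 (2.40) and AT1G47401 (2.1), and the lower were OPT3, AT3G01345 (-7.79), AT5G15360 (-4.56), AT3G30122 (-1.74) and AT5G34795 (-1.36), of which all but NEET and OPT3 are named after their values were seen. The IMA1 OE count was 61, 27 and 52 without EYFP deficient replicate 2 and IMA1 OE deficient replicates 1 and 2, and OPT3 in that line had adjusted p = 0.0581 without IMA1 OE deficient replicate 1. The IMA3 OE count was 28 without EYFP deficient replicate 1 and 1 without any of the other 3 libraries, and the opt3-2 count was 19 without EYFP deficient replicate 1 and 5 without opt3-2 deficient replicate 1. Calls ended in IMA1 OE for FER1 (0.105), FER4 (0.0574), VTL2 (0.162), FD2 (0.474), APX1 (0.338) and NRAMP4 (0.0667) without IMA1 OE deficient replicate 1. In IMA3 OE they ended for HCHIB (0.308) without EYFP deficient replicate 2 and NF-YA10 (0.518) without IMA3 OE deficient replicate 1. In opt3-2 they ended for NEET (0.388), AT3G43670 (0.0706) and AT1G47401 (0.267) without opt3-2 deficient replicate 1 and AT3G30122 (0.0506) and AT5G34795 (0.225) without opt3-2 deficient replicate 2. With the spread of the compared groups alone the counts were 2, 0 and 2 in limma, that of 0 with 612 genes at an unadjusted p under 0.05.

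The difference of responses showed weaker induction of iron uptake genes in roots of all 3 lines. For FRO2 the difference was -2.83 (SE 0.30, adjusted p = 0.00711) in IMA1 OE, -2.60 (SE 0.30, adjusted p = 0.0119) in IMA3 OE and -3.92 (SE 0.30, adjusted p = 0.000332) in opt3-2. For IRT1 it was -3.05 (adjusted p = 0.00851), -2.89 (adjusted p = 0.0127) and -4.30 (adjusted p = 0.000332). MTP3, a zinc and cobalt vacuolar transporter gene, was at -2.05, -1.63 and -2.52, and the phloem lectin-like gene PP2-A8 at -1.51, -1.44 and -1.90, all past the test with every library kept. IMA3 was at -4.62 (adjusted p = 0.00711) in IMA1 OE, -4.73 (adjusted p = 0.00878) in IMA3 OE and -2.18 (adjusted p = 0.116) in opt3-2, and OPT3 at -1.30, -1.10 and -2.09 (adjusted p = 1, 0.818 and 0.102). The glucosyltransferase gene UGT72E1 was at -2.0 in IMA1 OE and -1.84 in IMA3 OE, GulLO2 at -1.61 (SE 0.21, adjusted p = 0.0168) in IMA3 OE, and NAS2 at -2.71 (adjusted p = 0.000866) and COPT2 at -2.77 in opt3-2. WNK5 responded more in IMA1 OE (0.93, SE 0.11, adjusted p = 0.0123). Uptake genes with a weaker response numbered 3, 5 and 12 of 19 in IMA1 OE, IMA3 OE and opt3-2 (13, 17 and 17 when adjusted over the list alone), with adjusted p = 0.0356, 0.0195 and 0.0209 with an estimated correlation. Regulators numbered 4, 4 and 6 of 18 (11, 11 and 8 when adjusted over the list alone), with adjusted p = 0.0051, 0.0158 and 0.0209 with an estimated correlation, and transport genes 0, 1 and 4 of 16, with 0.00371, 0.0158 and 0.0209 as that p.

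The FRO2 and IRT1 differences came mostly (less so in IMA3 OE) from higher levels on control medium. In all, 14 genes passed in IMA1 OE (13 lower), 27 in IMA3 OE (23 lower) and 89 in opt3-2 (87 lower). Without EYFP deficient replicate 2 the counts were 2, 1 and 60, and in that case FRO2 (adjusted p = 0.059), IRT1, MTP3, PP2-A8 and UGT72E1 (0.067 each) did not pass in IMA1 OE, nor did FRO2 (0.0707), IRT1, PP2-A8 (0.0731 each) and UGT72E1 (0.0939) in IMA3 OE. The IMA1 OE count was 8 without IMA1 OE control replicate 1 or deficient replicate 2. The IMA3 OE count was 8, 9 and 13 without EYFP control replicates 1 and 2 and deficient replicate 1, and 10, 7, 66 and 41 without IMA3 OE control replicates 1 and 2 and deficient replicates 1 and 2. GulLO2 had adjusted p = 0.0791, 0.0589, 0.0507 and 0.0792 without EYFP control replicate 2, EYFP deficient replicates 1 and 2 and IMA3 OE control replicate 2. The opt3-2 count was 49 and 57 without EYFP control replicates 1 and 2, 50 and 52 without opt3-2 control replicates 1 and 2 and 48 without opt3-2 deficient replicate 1.

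Further calls of the difference in roots also moved. WNK5 had adjusted p = 0.0603, 0.0929, 0.0523 and 0.0586 without EYFP control replicate 1, EYFP deficient replicate 2, IMA1 OE control replicate 2 and IMA1 OE deficient replicate 1. In IMA1 OE, MTP3 had 0.0511 without IMA1 OE control replicate 1 and UGT72E1 0.0538 without deficient replicate 2. In IMA3 OE, MTP3 had 0.0798 and 0.131 without EYFP control replicates 1 and 2, 0.0874 and 0.147 without its deficient replicates and 0.165 and 0.0997 without IMA3 OE control replicates 1 and 2, PP2-A8 had 0.0618 without EYFP control replicate 1 and 0.0633 without IMA3 OE control replicate 2, UGT72E1 0.0776, 0.0627 and 0.078 without EYFP control replicates 1 and 2 and IMA3 OE control replicate 2, and IRT1 0.0661 without IMA3 OE control replicate 1. Without EYFP deficient replicate 1, OPT3 passed in IMA1 OE (-1.94, adjusted p = 0.0269) and opt3-2 (-2.72, adjusted p = 0.00259), and IMA3 in opt3-2 (-2.74, adjusted p = 0.0204). The 4 higher genes in IMA3 OE were AT2G01010 (3.84), AT5G38290 (0.81), ATCG00400 (4.79) and ATCG00920 (6.38), the last 2 plastid genes, and the 2 higher in opt3-2 were AT5G38290 (0.74) and AT1G47405 (2.16), all named after their values were seen. Their calls ended in IMA3 OE for AT2G01010 (0.165), ATCG00400 (0.106) and ATCG00920 (0.16) without IMA3 OE control replicate 1 and AT5G38290 (0.203) without EYFP control replicate 2. In opt3-2 they ended for AT5G38290 (0.151) without EYFP control replicate 2 and AT1G47405 (0.0895) without opt3-2 deficient replicate 1. IMA1 in IMA1 OE, at -3.36 (adjusted p = 0.0714), passed without EYFP control replicate 1 (-4.13, adjusted p = 0.00151) or replicate 2 (-2.58, adjusted p = 0.0262).

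**Figure D3:**
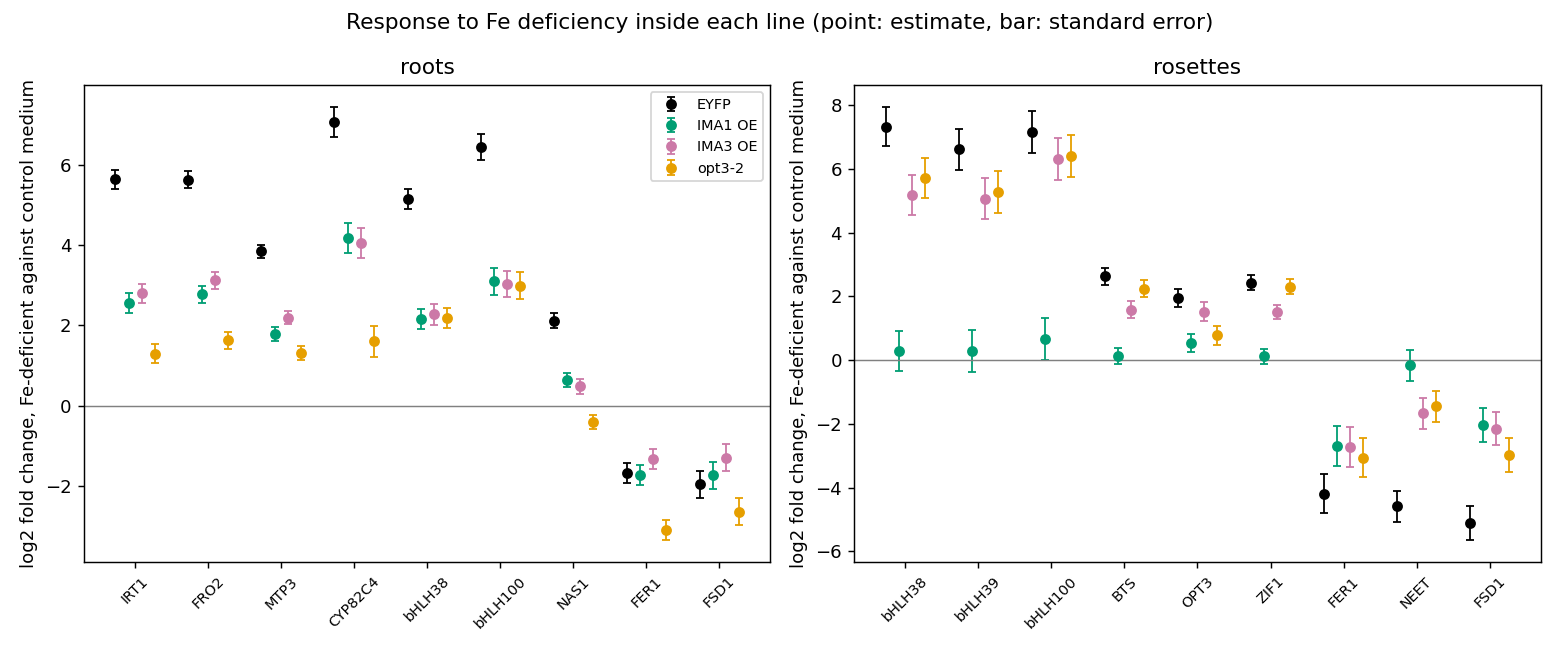
Log2 fold change between deficient and control medium inside each line for iron genes in roots (left) and rosettes (right), points being estimates and bars standard errors. For FRO2 in roots, the EYFP response of 5.63 exceeded that of opt3-2 by 3.92.

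In rosettes, the difference of responses passed for AT1G47407 alone in IMA1 OE (-5.33, adjusted p = 0.0091), a gene chosen after its value was seen. Regulators in IMA1 OE had 0 passing over all genes in limma and 9 of 18 lower when adjusted over the list alone (adjusted p = 0.0196 with an estimated correlation), with bHLH38 at -7.04 (adjusted p = 0.0557) and IMA1 at -5.29 (adjusted p = 0.0701). Transport genes had 5 lower when adjusted over the list alone, with adjusted p = 0.117 with an estimated correlation. IMA3 OE and opt3-2 had 0 in limma, with 252 and 438 genes at an unadjusted p under 0.05, against 363 in IMA1 OE. With a block for replicate number, 18 passed in IMA1 OE and 2 in opt3-2. The authors' tables hold no p-value for this contrast. The IMA1 OE count was 14 and 0 without EYFP control replicates 1 and 2, 31 without EYFP deficient replicate 1, 4 and 0 without IMA1 OE control replicates 1 and 2 and 0 without either deficient IMA1 OE library, and IMA1 passed without EYFP control replicate 1 (-6.25, adjusted p = 0.0116) or EYFP deficient replicate 1 (-5.61, adjusted p = 0.0457). IMA3 in IMA3 OE was at -0.91 and OPT3 in opt3-2 at -1.11 (adjusted p = 1 for both). For IMA3 OE the count was 6 without EYFP deficient replicate 1 and 1 without IMA3 OE control replicate 2, and for opt3-2 1 without EYFP deficient replicate 1 or opt3-2 control replicate 1.

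Within the lines, roots of all 3 still raised uptake genes under deficiency. In IMA1 OE 17 of 19 rose (18 when adjusted over the list alone), including the coumarin hydroxylase gene S8H (5.70) and MYB72 (5.25), with adjusted p = 0.0105 with an estimated correlation. In IMA3 OE 16 rose, FRO2 by 3.13, with adjusted p = 0.00817 with an estimated correlation, and in opt3-2 14 rose, with 0.0279 as that p. In these lines 6, 8 and 10 of 18 regulators rose (adjusted p = 0.0344, 0.00817 and 0.0183 with an estimated correlation), and in IMA3 OE IMA1 rose by 2.54 (adjusted p = 0.0124) while IMA3 was at 0.14. In IMA1 OE IMA1 was at -0.20, and in opt3-2 OPT3 was at 0.35 (adjusted p = 0.856). Of 7 storage genes 3 fell in IMA1 OE (VTL2 -3.21, VTL1 -2.38, FER1 -1.74, adjusted p = 0.0489 for the list with an estimated correlation), 1 in IMA3 OE (7 when adjusted over the list alone, adjusted p = 0.115 with an estimated correlation) and 6 in opt3-2 (FER1 -3.10, adjusted p = 0.0183 with an estimated correlation). In opt3-2, NAS2 (-2.21), FRD3 (-2.38) and NRAMP3 (-2.01) fell, as did FSD1 (-2.65) and the zinc transporter genes ZIP4 (-1.43), ZIP1 (-0.93) and ZIP3 (-1.2), the zinc list having adjusted p = 0.0361 with an estimated correlation. Altogether 230 genes passed in IMA1 OE (196 higher, 34 lower), 143 in IMA3 OE (129 higher, 14 lower) and 177 in opt3-2 (89 higher, 88 lower), and 81, 31 and 30 with a conservative standard error, which adds the variances of both deposited contrasts used. Counts without control replicates 1 and 2 and deficient replicate 1 of IMA1 OE were 150, 144 and 117, those without control replicates 1 and 2 and deficient replicate 2 of IMA3 OE 44, 42 and 43, and those without each opt3-2 library 74, 49, 88 and 76. Calls ended for FER1 (0.0516) without IMA1 OE control replicate 2, IMA1 (0.162) without IMA3 OE deficient replicate 2, and FSD1 (0.059) and ZIP3 (0.119) without opt3-2 control replicate 2.

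In rosettes, 0 genes passed within IMA1 OE in limma, with 267 at an unadjusted p under 0.05. There 5 of 7 storage genes were lower when adjusted over the list alone (FER1 -2.70, adjusted p = 0.0273 for the list with an estimated correlation). IMA3 OE rosettes had 7 genes higher, including bHLH100 (6.32), IMA1 (5.28), IMA2 (5.22), bHLH38 (5.17) and bHLH39 (5.07), with 5 of 18 regulators risen (9 when adjusted over the list alone, adjusted p = 0.0112 with an estimated correlation). In opt3-2 rosettes 8 of 18 regulators rose, among them bHLH100 (6.40), bHLH38 (5.72), IMA2 (3.86), IMA1 (3.79) and BTS (2.25), with adjusted p = 0.0419 with an estimated correlation. The ferritin gene FER3 (-1.85) and the ascorbate peroxidase gene APX1 (-1.98) fell, and ZIF1 (2.31) and NAS4 (1.61) rose. Of the jasmonate and wound list 0 passed over all genes in limma and 3 were lower when adjusted over the list alone, with JAZ5 at -1.60 and adjusted p = 0.0419 with an estimated correlation. The opt3-2 count was 43 (24 higher, 19 lower), and 1 with the conservative standard error, which gave 0 in IMA3 OE in limma, with 69 at an unadjusted p under 0.05. It was 7, 8 and 6 without opt3-2 control replicate 2 and deficient replicates 1 and 2. For IMA3 OE the count was 1 without control replicate 2 and 0 without any of its other 3 libraries, and for IMA1 OE 4 without control replicate 1. Calls ended in IMA3 OE for bHLH100 (0.114), IMA2 (0.0797) and bHLH39 (0.346) without deficient replicate 2, IMA1 (0.107) without control replicate 2 and bHLH38 (0.245) without control replicate 1. In opt3-2 they ended for bHLH100 (0.0609), bHLH38 (0.0842) and NAS4 (0.163) without deficient replicate 1 and IMA1 (0.257), IMA2 (0.136), BTS (0.126), FER3 (0.476) and APX1 (0.169) without control replicate 2.

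Lines on control medium were also set against EYFP on deficient medium. In roots and rosettes IMA1 was at 3.38 and 1.18 in IMA1 OE, IMA3 at -0.24 and -4.62 in IMA3 OE and OPT3 at -4.17 and -5.70 in opt3-2. The IMA3 call in rosettes ended (0.233) without EYFP deficient replicate 2. In roots, 17 of 19 uptake genes were lower in each of IMA1 OE, IMA3 OE and opt3-2 (adjusted p = 0.0168, 0.00995 and 0.0294 with an estimated correlation). All 7 storage genes were higher in IMA1 OE and in opt3-2 (adjusted p = 0.0168 and 0.0294 with an estimated correlation). In rosettes, 6, 4 and 5 storage genes were higher (adjusted p = 0.00929, 0.0161 and 0.0388 with an estimated correlation) and 9, 10 and 10 of 18 regulators lower (adjusted p = 0.0555, 0.0184 and 0.0842 with an estimated correlation). The counts were 467, 497 and 413 in roots and 189, 87 and 252 in rosettes, and single left-out libraries moved them by over 1.5 times as follows. In roots IMA1 OE had 225 without EYFP deficient replicate 2 and 271 without IMA1 OE control replicate 1, IMA3 OE had 296 without EYFP deficient replicate 2 and 289 and 267 without IMA3 OE control replicates 1 and 2, and opt3-2 had 174 without EYFP deficient replicate 2 and 184 and 182 without opt3-2 control replicates 1 and 2. In rosettes IMA1 OE had 120 and 106 without EYFP deficient replicates 1 and 2 and 72 and 112 without IMA1 OE control replicates 1 and 2, IMA3 OE had 47 without EYFP deficient replicate 2 and 42 and 38 without IMA3 OE control replicates 1 and 2, and opt3-2 had 123 and 144 without EYFP deficient replicates 1 and 2 and 36 without opt3-2 control replicate 2, the library with the most plastid transcripts.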

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

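The tests of the low IMA2 and IMA3 in IMA1 OE were chosen after that result was seen, and the others before their values were seen. SEs beside medians are of the mean over genes, not over libraries.

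IMA2 and IMA3, sisters of the overexpressed IMA1, were far lower in IMA1 OE than in EYFP on deficient medium, by -4.25 (SE 0.50) and -5.40 in roots and -7.22 and -7.88 in rosettes. An effect of reads shared by the 3 genes stays open, since -4.25, nearest 0, only restates the difference and how such reads were divided is not given. In roots the other 10 regulators that rose in EYFP had a median of -0.21 (SE 0.09) on deficient medium, above -2.41, which is 0.5 of the mean of IMA2 and IMA3, and 0 of them were called lower in limma, so an equally low level of all these regulators is argued against there. The same 10 responded more weakly than in EYFP, by a median of -0.83 (SE 0.41), against -2.27 for IMA2 and -4.62 for IMA3. That the 10 lay near EYFP on deficient medium argues against a weaker response of the line as the cause there. In rosettes the other 7 had a median of -6.39 (SE 1.02) and all 7 were lower, which is consistent with a weaker response of the whole tissue. Repression of the sister genes by the IMA1 transcript or peptide stays open as an untested hypothesis.

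The 2 EYFP control rosette libraries differed in iron genes, with FER1 at 56.5 and 282 RPKM in replicates 1 and 2, FSD1 at 396 and 669, IMA1 at 8.79 and 1.97, IMA2 at 11.0 and 4.52, IMA3 at 48.3 and 9.85 and OPT3 at 70.9 and 43.3, each in the direction of deficiency in replicate 1. Of 43 genes that changed with deficiency in opt3-2 rosettes, 28 differed in the direction of deficiency in replicate 1, with a median of 0.353. The highest such median between replicates in 5 other groups was 0.342, so replicate 1 may have been nearer to the deficient state, with a small margin over these 43 genes. Every rosette comparison with EYFP on control medium uses both libraries. Root tissue in replicate 1 is argued against. There 36 genes abundant in roots had a median of 0.161% of their root level, against 0.246% in replicate 2.

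Photosynthesis genes had a median of -0.99 in opt3-2 against EYFP roots on deficient medium, with 36 of 37 below 0. Leaf tissue in the EYFP root libraries would have lowered other leaf genes alike, but 246 nuclear genes abundant in rosettes had a median of -0.27 (SE 0.03). With each of the 4 libraries left out the median was -1.29, -0.78, -0.74 and -1.20, so no single library makes the difference. The list had adjusted p = 0.289 with an estimated correlation, so chance remains open. No biological explanation was tested.

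The other results stood out because a line responded differently from EYFP by the test of the difference of responses, because its log2 fold change had opposite signs in the 2 tissues in every library, called or not, or because a signal lay in features outside the comparisons. The tested differences passed for 14 genes in IMA1 OE, 27 in IMA3 OE and 89 in opt3-2 roots and for 1 gene in IMA1 OE rosettes. In IMA1 OE roots they were 0.93 for WNK5, -2.83 for FRO2, -1.51 for PP2-A8, -3.05 for IRT1, -2.0 for UGT72E1, -2.05 for MTP3 and -4.62 for IMA3. In IMA3 OE roots they were -2.60 for FRO2, -1.44 for PP2-A8, -2.89 for IRT1, -1.84 for UGT72E1, -1.61 for GulLO2 and -4.73 for IMA3. In opt3-2 roots they were -3.92 for FRO2, -4.30 for IRT1, -1.90 for PP2-A8, -2.71 for NAS2 and -2.52 for MTP3. List medians for regulators, transport and uptake were -0.70, -0.64 and -1.22 in IMA1 OE, -0.62, -0.60 and -1.61 in IMA3 OE and -0.72, -0.0505 and -2.22 in opt3-2 roots, and -1.54 for regulators in IMA1 OE rosettes.

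On control medium bHLH100 was at 3.20 (adjusted p = 0.00107 in limma) in roots and -1.40 (adjusted p = 0.758) in rosettes of IMA1 OE, and at 2.07 (adjusted p = 0.0318) and -1.46 (adjusted p = 1) in IMA3 OE. In opt3-2, ENH1 was at -1.08 (adjusted p = 0.323) in roots and 0.29 (adjusted p = 0.9) in rosettes, and DGAT3 at 0.37 (adjusted p = 0.358) and -1.14 (adjusted p = 0.203). Of these 8 values the 2 of bHLH100 in roots passed the test, and that in IMA3 OE did not pass without EYFP control replicate 1 or 2 (adjusted p = 0.275 and 0.187) or IMA3 OE control replicate 1 or 2 (0.194 and 0.265). The difference between tissues was not tested for any of these 4 pairs.

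The construct features carried signal in their own lines. The IMA1 overexpression construct had a mean of 294 RPKM in roots and 216 RPKM in rosettes of IMA1 OE, with at most 0.251 and 0.07 RPKM in a library of another line. The IMA3 construct had 37.2 and 28.3 RPKM in IMA3 OE, with at most 0.05 and 0.02 RPKM elsewhere. The YFP construct had 2165 and 136 RPKM in EYFP, with at most 0.705 and 0.095 RPKM elsewhere. The opt3-2 insertion had 0.999 and 1.34 RPKM in opt3-2, with at most 0.06 and 0.09 RPKM elsewhere.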

How the results depend on the processing

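The alternatives named above as added were chosen after the data were seen, and the others before. No gene call reversed its direction under any alternative run on it. Direction was not checked for list calls that ended or under the estimated correlation, and no other list call reversed. The split of counts was compared under centring, median-ratio scaling and a pseudocount of 1. Within opt3-2 roots 89 higher and 88 lower genes became 87 and 101 with centring, 87 and 99 with median-ratio scaling and 89 and 89 with a pseudocount of 1, so neither direction prevailed there. Counts of genes moved by over 1.5 times in 101 of 152 cases with 1 library left out, where a group keeps a lone library that is assumed to vary like the other groups. Of 76 calls of targeted genes and of genes named for a large change, which leave out list members and comparisons within lines or across media, 36 were lost with at least 1 single library left out and 40 were kept. Of 622 calls of list members over all comparisons 282 were lost and 340 kept, and of all 3788 calls 2537 were lost and 1251 kept, with no called gene turning its sign. Of list calls 46 held and 160 ended with the estimated correlation, 136 held at a preset correlation of 0.10, 169 at 0.05, 158 by the rank-based version and 173 on log2 fold changes. The cause of a moved count was not tested, except that a stricter threshold, another set of tested genes or fewer libraries act by construction. Depth is unknown, so no statement on genes not detected is made, and rosette counts rest on the spread pooled over 8 groups. Every alternative planned was run, the authors' p-values standing in for an adjusted p that the tables do not hold. Centring and median-ratio scaling kept the direction of every call among the targeted genes and those named for a large change, and were not run on single list members. The share of higher genes moved from 74.1% to 86.4% (19 higher, 3 lower) for IMA3 OE against EYFP in deficient roots with median-ratio scaling, and from 30.8% to 47.1% (8 higher, 9 lower) for IMA1 OE against EYFP in control rosettes with centring.

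Below, values in groups of 3 are for IMA1 OE, IMA3 OE and opt3-2. With 1 library left out, the EYFP response ranged from 282 to 372 genes in roots (530 with all libraries) and from 18 to 77 in rosettes (66). Against EYFP on control medium the ranges in roots were 31 to 64 (76), 7 to 15 (42) and 92 to 111 (200), and in rosettes 3 to 19 (13), 0 to 1 (0) and 3 to 138 (34). Against EYFP on deficient medium they were 13 to 35 (27), 5 to 76 (27) and 9 to 17 (18) in roots and 27 to 97 (103), 1 to 28 (7) and 5 to 19 (9) in rosettes. For lines on control medium against deficient EYFP they were 225 to 349 (467), 267 to 378 (497) and 174 to 335 (413) in roots and 72 to 120 (189), 38 to 81 (87) and 36 to 364 (252) in rosettes. Within the lines they were 117 to 184 (230), 42 to 203 (143) and 49 to 88 (177) in roots and 0 to 4 (0), 0 to 1 (7) and 6 to 64 (43) in rosettes. For the difference of responses they were 2 to 18 (14), 1 to 66 (27) and 48 to 83 (89) in roots and 0 to 31 (1), 0 to 6 (0) and 0 to 1 (0) in rosettes. Gene lists were not run with 1 library left out. The counts of 0 are from limma. With a library left out, between 551 and 675 genes had an unadjusted p under 0.05 where IMA3 OE had 0 on control medium in rosettes, 265 to 421 where IMA1 OE and 249 to 399 where IMA3 OE had 0 within the line, and 333 to 497, 196 to 346 and 309 to 565 where the differences of responses had 0.

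At an adjusted p of 0.01, roots had 280 genes in the EYFP response, 40, 13 and 95 on control medium, 2 for IMA3 OE on deficient medium, 239, 278 and 204 for lines on control medium against deficient EYFP, 135, 51 and 76 within the lines and 7, 2 and 46 for the difference of responses. Rosettes had 31 in the EYFP response, 3 (IMA1 OE) and 4 (opt3-2) on control medium, 53 (IMA1 OE) and 1 (IMA3 OE) on deficient medium, 82, 49 and 92 against deficient EYFP and 4 (IMA3 OE) and 14 (opt3-2) within the lines. With a limit of 2-fold, roots had 190 in the EYFP response, 111 for opt3-2 on control medium, 17 for IMA3 OE on deficient medium, 170, 187 and 167 against deficient EYFP and 103 (IMA1 OE) and 96 (opt3-2) within the lines. Shared higher genes in deficient roots were then 1 for IMA1 OE and IMA3 OE, 1 for IMA1 OE and opt3-2 and 3 for IMA3 OE and opt3-2, and the EYFP response shared 57 with opt3-2 on control medium.

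By the p-values of the authors' deposited tables, adjusted over all genes, roots had 150 in the EYFP response, 74 for opt3-2 on control medium, 72 (IMA3 OE) and 47 (opt3-2) on deficient medium and 164, 176 and 159 against deficient EYFP, and rosettes had 102, 34 and 162 on control medium and 176, 95 and 72 on deficient medium. With the spread of the compared groups alone, roots had 266 in the EYFP response, 8, 14 and 101 on control medium, 7, 2 and 7 on deficient medium and 119, 316 and 123 against deficient EYFP. Rosettes had 0 in the EYFP response, 0 (IMA1 OE) and 1 (opt3-2) on control medium, 2, 0 and 2 on deficient medium and 27, 20 and 10 against deficient EYFP. Beside these counts of 0 from limma, 341 genes had an unadjusted p under 0.05 in the EYFP response, 1084 in IMA1 OE and 712 in IMA3 OE (also 0) on control medium, and 612 in IMA3 OE on deficient medium.

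Without the genes of lowest expression, roots had 50 (IMA1 OE) and 26 (IMA3 OE) on control medium, 62 (IMA3 OE) and 110 (opt3-2) within the lines and 15 (IMA3 OE) for the difference of responses. Rosettes had 2 (IMA3 OE) and 15 (opt3-2) on control medium, 22 (IMA3 OE) and 16 (opt3-2) on deficient medium, 3 (IMA1 OE) and 3 (IMA3 OE) within the lines and 9, 5 and 7 for the difference of responses. With all genes, roots had 262 for opt3-2 against deficient EYFP, 76 (IMA3 OE) and 96 (opt3-2) within the lines and 26 (IMA1 OE) and 41 (IMA3 OE) for the difference of responses. Rosettes had 21 (IMA1 OE) and 7 (IMA3 OE) on control medium, 28 (IMA3 OE) and 34 (opt3-2) on deficient medium, 161 for opt3-2 against deficient EYFP, 11 (IMA1 OE) within the line and 23, 14 and 29 for the difference of responses.

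With the conservative standard error, 81, 31 and 30 genes passed within the lines in roots and 0 (IMA3 OE, limma, 69 at an unadjusted p under 0.05) and 1 (opt3-2) in rosettes, and the route through the other EYFP group left all 12 counts within 1.5 times. Without the library with the most plastid transcripts, roots had 43 within IMA3 OE and 41 for its difference of responses. Rosettes had 4 for opt3-2 on control medium, 1 for IMA3 OE on deficient medium, 36 for opt3-2 against deficient EYFP, 7 within opt3-2 and 3 for the difference of responses of IMA1 OE. The count of IMA3 OE on control medium in rosettes was 1 with median-centred fold changes, 1 with median-ratio scaling and 1 with a pseudocount of 1, and the last gave 7 for the difference of responses of IMA1 OE in rosettes. List calls numbered 103 in roots and 103 in rosettes, 62 in rosettes at a preset correlation of 0.10, and 29 and 17 with the estimated correlation.

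A replicate block, pairing libraries by replicate number, was run although the labels do not state such pairs. Across genes, replicate differences correlated positively in 28 of 28 group pairs in roots and 27 of 28 in rosettes. In 26 and 27 pairs r was over 0.1 (median 0.233 and 0.369, lowest 0.0189 and -0.00956). A shared replicate effect, left in the spread of the main test, stays open. With the block, roots had 863 in the EYFP response, 90 (IMA3 OE) and 474 (opt3-2) on control medium, 48, 115 and 110 on deficient medium, 760, 873 and 759 against deficient EYFP, 432 within opt3-2 and 140 for its difference of responses. Rosettes had 73, 2 and 200 on control medium, 232, 24 and 15 on deficient medium, 451, 157 and 653 against deficient EYFP, 2, 13 and 87 within the lines and 18 (IMA1 OE) and 2 (opt3-2) for the difference of responses.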

Other observations

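The genes of the next 2 paragraphs were chosen after their values were seen, and no test beyond those of the report was run on them.

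Some genes differed from EYFP on both media, whatever the iron supply. In roots 11 genes were higher on both media in IMA1 OE, 11 in IMA3 OE and 8 in opt3-2, and 4, 1 and 5 were lower. A subtilase-like gene, AT2G05920, was at 2.53 and 2.59 on control and deficient medium in IMA1 OE roots, 2.53 and 2.57 in IMA3 OE and 2.45 and 2.60 in opt3-2. GLP4, a germin-like protein gene, OSM34, an osmotin-like protein gene, the chitinase gene ChiC, ACS and AT4G25310 were also higher on both media in roots of all 3 lines. Since all 3 lines were compared with the same EYFP libraries, a difference of the EYFP line itself and a shared difference of the 3 lines are not separated by these values.

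In rosettes 2 genes were higher and 6 lower on both media in IMA1 OE, 0 and 0 in IMA3 OE, and 0 and 4 in opt3-2. The urea transporter gene DUR3 was at 1.51 and 1.40 in IMA1 OE. AT3G01345 was lower in both tissues and on both media in IMA1 OE (-7.35, -7.70, -7.47 and -7.84 in roots on control and deficient medium and rosettes on control and deficient medium) and in opt3-2 (-7.84, -7.78, -7.56 and -7.79), and AT5G15360 was at -5.91, -5.85, -4.89 and -4.65 in IMA1 OE and at -6.27, -6.25, -4.87 and -4.56 in opt3-2. OPT3 itself was lower in all 4 comparisons of opt3-2, at -1.74, -3.83, -3.80 and -4.91.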
